A study of Mus musculus with 12 samples.

How the data were processed

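The series profiled polyadenylated RNA of astrocytes from the mouse cerebral cortex at postnatal day 14 in a design of genotype by early life stress. Per the labels, Cre- animals carry a floxed glucocorticoid receptor gene (Nr3c1), and AGR cKO animals carry in addition the Aldh1l1-CreERT2 transgene, a tamoxifen-activated recombinase expressed in astrocytes. Pups of the stressed groups, called ESD in the labels, spent 3 hours a day away from the dam from postnatal day 1 to 14. Animals of all 4 groups received 4-hydroxytamoxifen from day 5 to 7. Astrocytes were purified by immunopanning and magnetic beads. Per the labels' protocols, RNA with an integrity number over 7.0 entered stranded mRNA library preparation at 1 µg per sample. Each group has 3 libraries, 12 in all.

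Groups were taken from the sample titles. The genotype entries of the labels carry a number that counts up with the replicate (Nr3c1, Nr3c2, Nr3c3) in some groups, and the titles were followed instead. The column names give the condition and "cre_M" or "cre_P", read here as Cre minus and Cre plus; the labels do not spell this out. Nr3c1 was lower in every library so read as Cre plus than in every library read as Cre minus.

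The authors deposited read counts per gene and per transcript as whole numbers, with no further normalization stated. Per the file headers, the same tables hold FPKM values, fragments scaled by length and library size. The deposited tables also hold TPM values, transcript levels that sum to the same total, for each library. The submitters' processing notes name Trimmomatic, HISAT2 2.1.0, HISAT, Bowtie2, StringTie 1.3.4b and DESeq2 and genome build mm10, without the role or the order of each tool. How whole counts were derived, and whether counting used the strand, is not stated. The gene table has 45777 genes, and there are 129299 transcripts. Coordinates below are mm10 positions of the genes as annotated for that build.

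Tests used the deposited gene counts. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 19163 genes. Library sizes were scaled with TMM factors, and a quasi-likelihood negative binomial model with 1 mean per group was fitted over all 12 libraries, with 8 residual degrees of freedom. The common biological coefficient of variation was 0.1945. The 5 contrasts were stress within each genotype, genotype within each condition, and their interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. The standard error of a log2 fold change is its size over the square root of the F statistic. Levels are CPM, counts scaled by library size, given as mean ± SD of 3 libraries. With 3 libraries against 3, an exact two-sided permutation test of a single gene cannot go below 0.1, so single genes were tested in the shared model.

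Gene lists, 22 in all with 355 symbols, were fixed before the data were examined, as were the tests, the contrasts, the named genes' rule and most of the alternative settings below. All 355 symbols were in the table, 13 of them under the mitochondrial names the table uses, and 352 were tested. The lists cover glucocorticoid-responsive genes, engulfment receptors and their partners, lysosome and phagosome, astrocyte synapse-regulating factors, pan-reactive, A1-type and A2-type reactive astrocyte genes, interferon-stimulated genes, immediate early and heat shock genes, cholesterol synthesis, cell cycle, and mitochondrial and nuclear oxidative phosphorylation genes. Marker lists cover astrocytes, microglia and macrophages, neurons, oligodendrocytes and their precursors, endothelium, mural cells and fibroblasts, ependyma and choroid plexus, and erythroid cells. Gfap stands in both the astrocyte and the pan-reactive list, and Sox10 in both oligodendrocyte lineage lists. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 22 lists within each contrast. Each list was also tested with an estimated correlation and with fry.

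Genes named in the text follow a fixed rule. Per pairwise comparison it takes, among called genes with a mean of at least 5 CPM, no overlap in CPM between the groups and a symbol that is not a predicted model, the 12 highest and the 12 lowest log2 fold changes. The interaction takes 6 each way. A comparison with fewer than 6 calls gives up to 5 genes with the smallest p, as values. Nr3c1, Mertk, Megf10, Axl, Fkbp5, Tsc22d3, Sgk1 and Aldh1l1 are always given. From each list up to 4 called members are taken, or up to 2 with the smallest p where none is called.

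The alternative settings chosen then were DESeq2 1.42.0, median-of-ratios and upper-quartile scaling, other filters on low counts, only the libraries of the groups compared, a block on replicate number, each library left out in turn, other thresholds, limma-trend on deposited TPM with added values of 1 and 0.1, and single transcripts of Nr3c1 and Mertk. Robust moderation, a covariate of microglial and endothelial marker level, the contrasts averaged over the other factor and the list tests with each library left out in turn were added after the data had been seen.

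The procedure was tested on simulated counts with 200 changed genes, drawn from genes with a mean of at least 5 CPM. Recovery of single genes below that level was not measured. In the simulated comparison of the ESD groups across genotypes (18815 genes), edgeR recovered 53.7% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 11 of 18572 unchanged genes called. DESeq2 recovered 71.6%, 94.0% and 98.5% and called 51 of 18920 unchanged genes. That is 0.353% of the unchanged genes to which it gave an adjusted p, against 0.0592% in edgeR. DESeq2 thus called more unchanged genes than edgeR here, a limit on its larger counts below. For stress within Cre- animals (18832 genes) edgeR recovered 43.3%, 92.5% and 98.5%, and for stress within AGR cKO animals (18798 genes) 47.8%, 92.5% and 98.5%. For genotype in control animals (18814 genes) the shares were 35.8%, 83.6% and 98.5%, and for the interaction (18819 genes) 14.9%, 44.8% and 95.5%. The 2 changed lists, with every member raised 1.5-fold, were recovered in each simulated contrast. Smaller changes of a list were not simulated. Of 20 unchanged lists 1 was called for the interaction at the preset correlation and 0 in the other contrasts, but simulated genes are independent, unlike real ones.

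Library totals ran from 4.26e+07 to 5.21e+07 counts, where 3 counts in a library stand for 0.0575 to 0.0704 CPM. Within-group correlations of log2 CPM over genes ran from 0.971 to 0.989, and chi-square statistics per degree of freedom ran from 10.0 to 101 over the 12 within-group pairs, where resequenced copies of 1 library would lie near 1. Raw reads, FPKM values and the sex of the animals were not analysed here.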

Results

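The data are bulk RNA sequencing profiles of purified cortical astrocytes from 14-day-old mice in 4 groups of 3 libraries: Cre- control, Cre- ESD, AGR cKO control and AGR cKO ESD. AGR cKO stands for deletion of the glucocorticoid receptor in astrocytes, and ESD for daily separation from the dam. Total counts were 4.26e+07 to 4.37e+07 in Cre- control, 4.71e+07 to 5.07e+07 in Cre- ESD, 4.34e+07 to 4.98e+07 in AGR cKO control and 4.43e+07 to 5.21e+07 in AGR cKO ESD libraries. The 10 most abundant genes took 8.16% to 10.8% of counts, and mitochondrial transcripts 3.38% to 4.66%. Levels below are CPM (counts scaled by library size), mean ± SD of n = 3 libraries per group, and log2 fold changes carry their standard error. Adjusted p-values come from edgeR quasi-likelihood tests with Benjamini-Hochberg correction over 19163 genes, unless another test is named.

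Nr3c1 (gene ID 14815, chromosome 18, 39410545 to 39519421), the targeted gene, separated the genotypes in all 12 libraries. It stood at 214, 210 and 237 CPM in the Cre- control libraries and 209, 205 and 199 CPM in the Cre- ESD libraries. The AGR cKO control libraries held 102, 93.2 and 108 CPM, and the AGR cKO ESD libraries 90.5, 66.6 and 95.9 CPM. The log2 fold change in AGR cKO was -1.12 ± 0.12 in control animals (adjusted p = 0.0167) and -1.28 ± 0.12 under ESD (adjusted p = 0.00459). The control value did not pass without Cre- control 2 (adjusted p = 0.067), Cre- control 3 (0.0749), AGR cKO control 1, 2 or 3 (0.11, 0.118 and 0.108) or Cre- ESD 2 (0.0554), and did without any 1 of the other libraries. Gene counts take in every exon and the labels do not give the deleted one, so transcripts that lack it are counted too. For stress the log2 fold change of Nr3c1 was -0.11 ± 0.12 in Cre- and -0.26 ± 0.12 in AGR cKO, not called in either (adjusted p = 0.869 and 0.656).

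**Figure D1:**
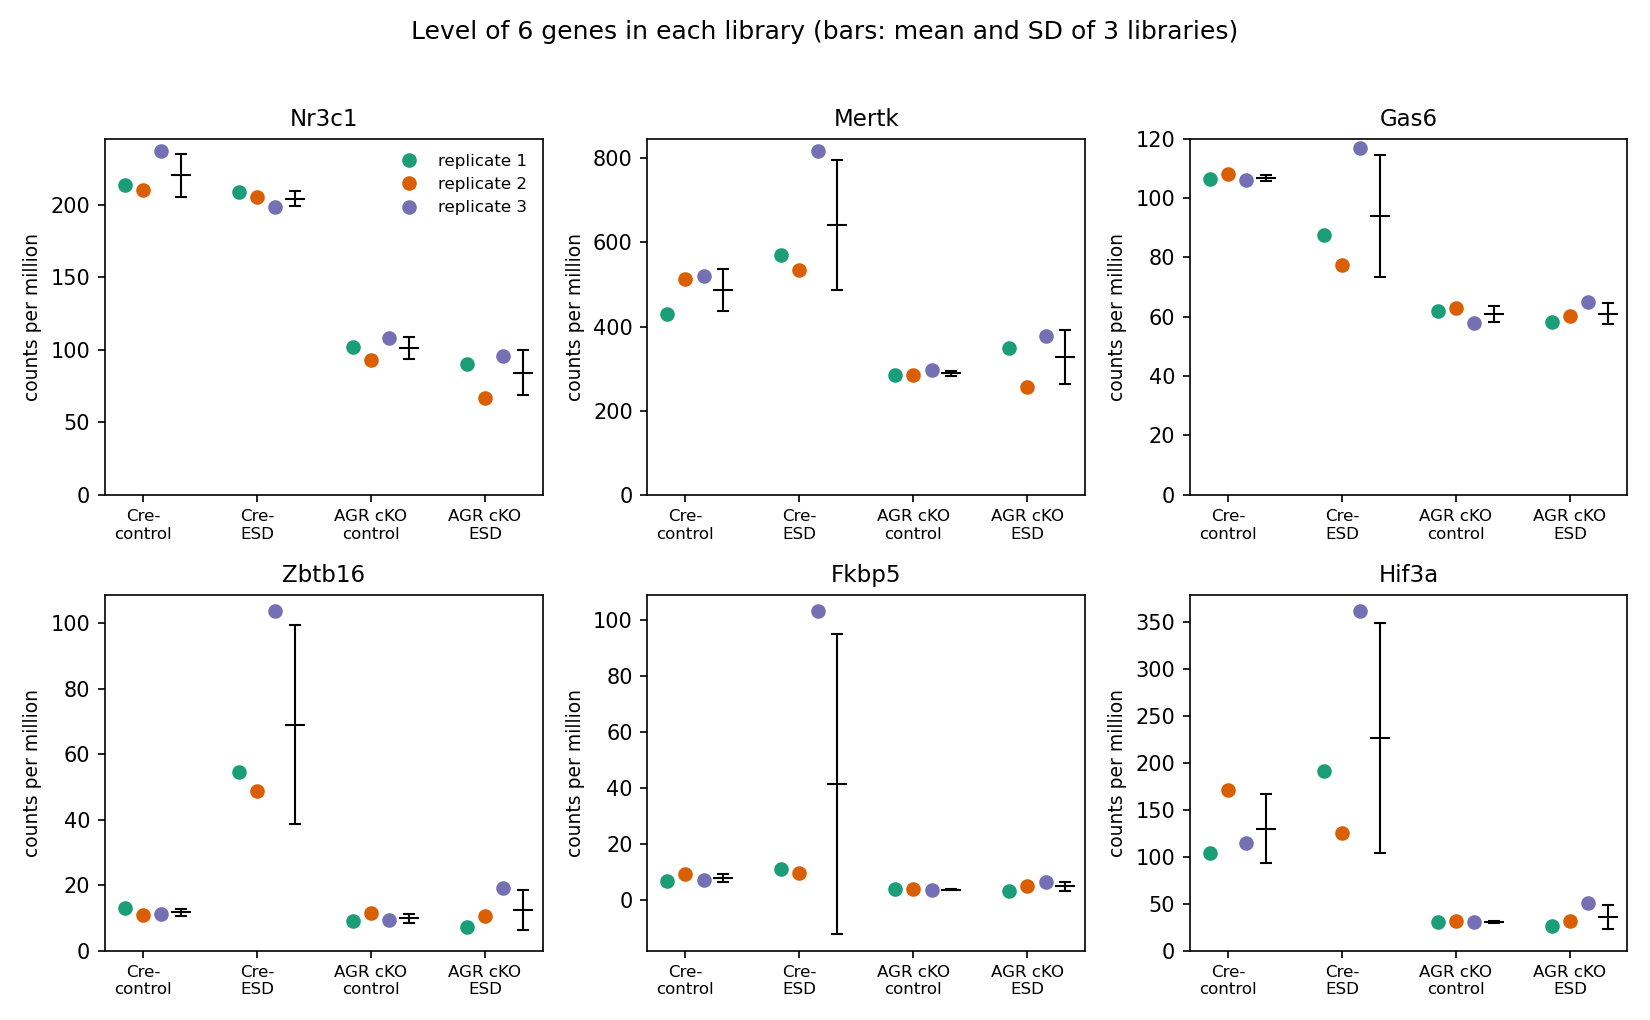
CPM of 6 genes in each of the 12 libraries, by group, with replicate numbers in colour and the mean and SD of 3 libraries as bars. Nr3c1 and Hif3a are lower in every AGR cKO library than in every Cre- library, Zbtb16 is at 48.7 to 104 CPM in the Cre- ESD libraries against 10.8 to 13.0 in Cre- control, and Fkbp5 is high in the third Cre- ESD library alone.

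The comparison of Cre- ESD with Cre- control asks how astrocytes with an intact receptor respond to early separation from the dam, and the series title names Mertk as the gene of interest. Zbtb16 (chromosome 9, 48651797 to 48836225), a zinc finger transcription factor known to be induced by glucocorticoids, had the smallest p. It stood at 11.7 ± 1.14 CPM in control and 69.0 ± 30.3 CPM in ESD libraries, higher in 3 of 3, with a log2 fold change of 2.56 ± 0.35 that did not pass the correction (adjusted p = 0.194). Mertk (chromosome 2, 128698915 to 128803162), a receptor tyrosine kinase for the engulfment of cells and debris, stood at 487 ± 50.2 CPM in control and 641 ± 155 CPM in ESD libraries. Its log2 fold change of 0.40 ± 0.17 was not called (adjusted p = 0.691) and was 0.18 without Cre- ESD 3, which alone held 818 CPM. Fkbp5, a co-chaperone of the receptor and a classical glucocorticoid-induced gene, was at 103 CPM in Cre- ESD 3 and at 11.1 and 9.9 CPM in the other Cre- ESD libraries, against 7.85 ± 1.47 CPM in control.

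In edgeR 0 genes were called for stress in Cre- animals, with 1378 at an unadjusted p under 0.05, of which 517 were higher and 861 lower. DESeq2 called 24, and limma-trend on TPM 0. Zbtb16 was the only gene called in a fit that left out 1 library, and only without AGR cKO ESD 3 (adjusted p = 0.0338). After Zbtb16 the smallest p-values belonged to Gm40469, Bcorl1, Slc8b1 and Ampd2. Gm40469, a predicted gene, had no count in the Cre- control libraries and 0.23 ± 0.07 CPM in ESD. Bcorl1, a transcriptional corepressor, was at -0.40 ± 0.07, Slc8b1, the mitochondrial sodium-calcium exchanger, at -0.48 ± 0.08, and Ampd2, an AMP deaminase, at -0.54 ± 0.09 (adjusted p = 0.317 each). Megf10 and Axl, the other engulfment receptors given throughout, showed 206 ± 34.0 against 206 ± 28.6 CPM and 412 ± 41.3 against 437 ± 19.0 CPM. Aldh1l1, the marker gene whose promoter drives the recombinase, showed 444 ± 59.4 against 530 ± 12.5 CPM (adjusted p = 0.708).

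Of the 22 lists, camera called 4 for stress in Cre- animals. Glucocorticoid-responsive genes were higher in 20 of 23 (median log2 fold change 0.12, adjusted p = 0.00967), none called and 1 adjusted over the list alone; with an estimated correlation the adjusted p = 0.942. Without Cre- ESD 3 the direction of that list turned (adjusted p = 0.63). Ependymal and choroid plexus markers were lower in 10 of 10 (median -0.57, adjusted p = 0.00236, and 0.942 with an estimated correlation), among them Foxj1, a regulator of motile cilia, at -0.78 ± 0.21 and Ccdc153 at -0.90 ± 0.31. Cholesterol synthesis genes were lower in 14 of 20 (median -0.08, adjusted p = 0.0222, 0.942 with an estimated correlation, and 0.262 without Cre- ESD 3), with Mvd at -0.35 ± 0.08 and 3 members passing when adjusted over the list alone. Nuclear oxidative phosphorylation genes were higher in 20 of 22 (median 0.10, adjusted p = 0.000372, and 0.942 with an estimated correlation). With 1 library left out, the ependymal call alone stayed in every fit. Glucocorticoid-responsive genes were not called without Cre- control 2 (adjusted p = 0.0705), cholesterol synthesis without Cre- control 3 (0.43) and oxidative phosphorylation without Cre- control 1 (0.29). Engulfment genes (8 of 20 higher, adjusted p = 0.554) and lysosome and phagosome genes (14 of 22 higher, adjusted p = 0.14) were not called.

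The comparison of AGR cKO ESD with AGR cKO control asks which stress differences remain when astrocytes lack the receptor. Genes of neurons were among those with the smallest p: Sez6l2, a neuronal membrane protein, at -1.16 ± 0.18, Slc17a7, a vesicular glutamate transporter, at -1.80 ± 0.33, and Ptprn, a protein of dense-core vesicles, at -1.23 ± 0.23. Nptx2, a secreted neuronal pentraxin, went the other way at 0.66 ± 0.12. Their adjusted p-values of 0.488 to 0.647 did not pass. Mertk was at 288 ± 6.58 CPM in control and 327 ± 63.7 CPM in ESD libraries (0.18 ± 0.17, adjusted p = 0.85), and Zbtb16 at 9.81 ± 1.34 and 12.3 ± 6.06 CPM.

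In edgeR 0 genes were called for stress in AGR cKO animals, with 1453 at an unadjusted p under 0.05, of which 623 were higher and 830 lower. DESeq2 called 17, limma-trend on TPM 0, and edgeR with the microglial and endothelial covariate 1. Camera called 11 lists, none of which was kept with an estimated correlation. Neuron markers were lower in 19 of 19 (median -0.74, adjusted p = 1.4e-11), with Syt1, a synaptic vesicle protein, at -1.51 ± 0.35 and 7 members passing when adjusted over the list alone. The list had an adjusted p = 0.0572 with an estimated correlation, and passed that test without Cre- control 3 (0.0307) or Cre- ESD 1 (0.0114). Mural cell and fibroblast markers were lower in 12 of 13 (median -0.73, adjusted p = 1.54e-06, and adjusted p = 0.461 with an estimated correlation), with Col3a1 at -0.85 ± 0.26 and Pdgfrb at -0.65 ± 0.25. Erythroid genes (5 of 5 lower, adjusted p = 0.000166), interferon-stimulated genes (17 of 18 lower, 0.0019), mitochondrial transcripts (13 of 13 lower, 0.00199), A1-type (8 of 10 lower, 0.0241) and A2-type reactive genes (10 of 12 lower, 0.0444) were also called. Astrocyte markers (18 of 20 higher, adjusted p = 0.00763), cholesterol synthesis (18 of 20 higher, 0.00087), nuclear oxidative phosphorylation (22 of 22 higher, 0.00023) and cell cycle genes (20 of 21 higher, 0.0373) were called the other way. The adjusted p of these 9 lists with an estimated correlation lay between 0.461 and 0.74. With 1 library left out, 4 of the 11 calls stayed in every fit, those of neuron, mural, erythroid and cholesterol genes. Cell cycle and interferon-stimulated genes changed direction without AGR cKO ESD 1 (adjusted p = 0.443 and 0.87). That library stood at 0.80 and -0.97 for these lists, against -0.07 and 0.44 in AGR cKO ESD 2 and -0.26 and -0.12 in AGR cKO ESD 3. Without it A1-type (adjusted p = 0.443), A2-type (0.17), astrocyte (0.17) and nuclear oxidative phosphorylation genes (0.262) were not called either, nor were mitochondrial transcripts without AGR cKO ESD 2 (0.137).

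The comparison of AGR cKO control with Cre- control asks what loss of the astrocyte receptor changes without added stress. Besides Nr3c1, Zfp868 (chromosome 8, 69610654 to 69625557), a zinc finger gene, rose from 12.4 ± 1.13 to 23.8 ± 2.40 CPM (0.94 ± 0.12, adjusted p = 0.0396). LOC115486910, a long non-coding RNA (chromosome 8, 60719256 to 60725882), rose from 0.81 ± 0.11 to 3.16 ± 0.44 CPM (1.96 ± 0.25, adjusted p = 0.0396). Short of the threshold, Gas6, the ligand that bridges Mertk to dying cells and membrane debris, stood at 107 ± 1.10 CPM in Cre- and 60.8 ± 2.75 CPM in AGR cKO libraries (-0.81 ± 0.12, adjusted p = 0.0818). Mertk stood at 487 ± 50.2 and 288 ± 6.58 CPM (-0.76 ± 0.17, adjusted p = 0.226), lower in every AGR cKO control library than in every Cre- control library. Dok6, a signalling adaptor, was at 0.78 ± 0.12 and Grin1, an NMDA receptor subunit, at 1.03 ± 0.16 (adjusted p = 0.0818 each).

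For AGR cKO control versus Cre- control edgeR called 3 genes, 1 lower and 2 higher, with 1958 at an unadjusted p under 0.05. DESeq2 called 265, of which 80 were higher and 185 lower, and limma-trend on TPM called 3. With the microglial and endothelial covariate edgeR called 0 higher and 3 lower genes, so Zfp868 and LOC115486910 were not called there. Of the 3 genes called without the covariate, 1 kept its call. Without the covariate the edgeR count was 63 without Cre- ESD 3 (24 higher, 39 lower) and 31 with the 6 control libraries alone (10 higher, 21 lower). It was 2 without Cre- control 1 or AGR cKO ESD 2 and 1 without AGR cKO ESD 1 or 3. It was 0 without Cre- control 2, Cre- control 3, Cre- ESD 2 or any of the AGR cKO control libraries. Without Cre- ESD 3, which shares the spread estimate but is not compared, Gas6 (adjusted p = 0.00227), Dok6 (0.0273), Mertk (0.0477), Tsc22d3 (0.0478), Hif3a (0.0146), Mfsd2a (0.0336), Grin1 (0.0316) and S100a10 (0.0273) passed the threshold, and Grin1 also without AGR cKO ESD 2 (adjusted p under 0.05).

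Camera called 8 lists for genotype in control animals. Glucocorticoid-responsive genes were lower in 23 of 23 (median -0.67, adjusted p = 5.92e-10), with 9 passing when adjusted over the list alone and none over all genes; with an estimated correlation the adjusted p = 0.31. Among them Hif3a, a hypoxia-inducible factor subunit, stood at 130 ± 36.4 against 30.7 ± 1.01 CPM (-2.08 ± 0.36), and Mfsd2a, a lysophospholipid transporter, at -1.26 ± 0.30 (adjusted p = 0.109 and 0.23). Tsc22d3, a leucine zipper protein induced by glucocorticoids, was at -0.88 ± 0.31, Sgk1, a hormone-regulated kinase, at -0.68 ± 0.29 and Fkbp5 at -1.03 ± 0.73 (adjusted p = 0.362, 0.439 and 0.677). Cholesterol synthesis genes were higher in 19 of 20 (median 0.22, adjusted p = 1.22e-08, and adjusted p = 0.16 with an estimated correlation), led by Hmgcs1 at 0.51 ± 0.12 and Lss at 0.37 ± 0.10, with 7 members passing when adjusted over the list alone. Neuron markers were higher in 17 of 19 (median 0.49, adjusted p = 1.16e-06, and adjusted p = 0.16 with an estimated correlation), Slc17a7 among them at 1.51 ± 0.33.

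Markers of other cell types differed between the genotypes in the same libraries. Microglia and macrophage markers were lower in 20 of 20 in AGR cKO control (median -1.06, adjusted p = 2.65e-09) and endothelial markers in 14 of 14 (median -0.98, adjusted p = 0.00562). Both calls were lost with an estimated correlation (adjusted p = 0.477 and 0.765). Endothelial markers stood at 1.68 in Cre- control 1 and at -0.65 and 0.24 in Cre- control 2 and 3, against -0.72, -0.39 and 0.37 in AGR cKO control. They were not called without Cre- control 1 (adjusted p = 0.984) or AGR cKO control 1 (0.124), while the microglial call stayed in every fit. The microglial level was 1.25, -0.20 and 0.31 in Cre- control and -0.97, -0.63 and 0.13 in AGR cKO control. Ependymal markers were lower in 9 of 10 (median -0.96, adjusted p = 2.21e-06, and adjusted p = 0.31 with an estimated correlation), with Tmem212 at -1.36 ± 0.29 and Ccdc153 at -1.42 ± 0.32. Immediate early and heat shock genes were lower in 15 of 17 (adjusted p = 0.00273) and mitochondrial transcripts higher in 13 of 13 (adjusted p = 0.0016); with an estimated correlation both had an adjusted p = 0.672. The first was lost without Cre- control 3 (adjusted p = 0.681) and the second without Cre- control 1 (0.295). Oligodendrocyte markers (6 of 13 higher, adjusted p = 0.889) and precursor markers (6 of 12 higher, adjusted p = 0.855) were not called. A1-type reactive genes (9 of 10 lower, adjusted p = 0.0645) were called without Cre- ESD 3 (adjusted p = 0.0421), and not with an estimated correlation (0.728).

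The comparison of AGR cKO ESD with Cre- ESD asks what the receptor contributes in stressed animals. In the edgeR fit over all 12 libraries it gave the most calls of the planned comparisons. Genotype in control gave more with only the groups compared (31 against 0), without Cre- ESD 3 (63 against 25) and without Cre- ESD 1 (3 against 2). Hif3a fell from 226 ± 122 to 35.9 ± 12.6 CPM (-2.65 ± 0.36, adjusted p = 0.0185) and Zbtb16 from 69.0 ± 30.3 to 12.3 ± 6.06 CPM (-2.49 ± 0.35, adjusted p = 0.0185). Mertk fell from 641 ± 155 to 327 ± 63.7 CPM (-0.97 ± 0.17, adjusted p = 0.0326), and its ligand Gas6 from 93.9 ± 20.6 to 61.0 ± 3.50 CPM (-0.62 ± 0.12, adjusted p = 0.0431). Vcan, which encodes the matrix proteoglycan versican, rose from 110 ± 33.1 to 249 ± 17.5 CPM (1.18 ± 0.19, adjusted p = 0.0277), and Mvd, an enzyme of the mevalonate pathway, from 54.6 ± 2.07 to 86.7 ± 7.34 CPM (0.67 ± 0.08, adjusted p = 0.0156). In each of these 6 genes the 3 libraries of one genotype did not overlap the 3 of the other under ESD. The naming rule requires this of genes taken by fold change, such as Hif3a, Zbtb16 and Vcan, so for them it is no separate result. Microglial and endothelial markers were lower in the same AGR cKO libraries.

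In edgeR 200 genes were called, 112 higher and 88 lower in AGR cKO, with log2 fold changes of 0.31 to 7.39 in size and 54 at 2-fold or more. At an unadjusted p under 0.05 there were 2989, DESeq2 called 783, 197 of the 200 among them, and limma-trend on TPM with 1 added called 142. Among the highest by the rule were Them4 at 1.15 ± 0.16, C1ql3, a synaptic organiser of the C1q family, at 1.11 ± 0.20, Pcdh8, a protocadherin, at 1.01 ± 0.17, Zfp868 at 1.00 ± 0.12, Cntnap2, a neurexin-like adhesion protein, at 0.99 ± 0.19, and S100a10 at 0.98 ± 0.17. Kcnh5, Wnt7a, Gas7, Il17d and Vipr2 followed at 0.89 to 0.96. Among the lowest were Cdh19, a cadherin, at -2.40 ± 0.41, Asic2, an acid-sensing ion channel, at -2.19 ± 0.41, Map7d2 at -2.16 ± 0.31, Nrros at -2.09 ± 0.43, and Arhgef28 at -1.88 ± 0.37. Mycl, Adamts20, Cables1, Lgi1, a secreted synaptic protein, and Cntn1, a contactin, were at -1.83 to -1.52. Adjusted p-values of these genes ran from 0.0154 to 0.046.

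The 200 depends on which libraries share the fit. It was 0 with the 6 ESD libraries alone, 100 without a filter on low counts and 112 with the microglial and endothelial covariate. With the covariate 29 were higher and 83 lower in AGR cKO, and only 70 of the 200 were among them. Leaving out 1 library gave 2 without Cre- ESD 1, 13 without AGR cKO control 2, 14 without AGR cKO ESD 1, 25 without Cre- ESD 3, 48 without AGR cKO ESD 3, 53 without AGR cKO control 1, 56 without AGR cKO control 3, 66 without AGR cKO ESD 2 and 67 without Cre- control 3. All 200 kept their direction in each of these 9 fits, which keep all or most of the compared libraries. The 200 were selected in those libraries, so kept direction is no separate support for them. Mertk passed the threshold without Cre- control 1, Cre- control 2 or Cre- ESD 2 and not without any of the other 9 libraries, with a log2 fold change of -1.09 to -0.76 and an adjusted p of 0.0254 to 0.108 over the 12 fits.

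Cholesterol synthesis genes rose together in AGR cKO under ESD. All 20 were higher (median 0.35, camera adjusted p = 7.73e-18, and adjusted p = 0.02 with an estimated correlation), 7 were called over all genes and 18 adjusted over the list alone. Called enzymes were Mvd, Fdps at 0.58 ± 0.08, Lss at 0.51 ± 0.10, Dhcr7 at 0.47 ± 0.09, Cyp51 at 0.45 ± 0.09, Nsdhl at 0.38 ± 0.06 and Sqle at 0.31 ± 0.06. Without Cre- ESD 3 the list kept its call with an estimated correlation (adjusted p = 0.0349), and it did not without Cre- ESD 2 (0.0559), AGR cKO ESD 2 (0.0661) or AGR cKO ESD 3 (0.0687). It was the only one of the 13 lists called in this comparison that kept its call with an estimated correlation. With replicate number as a block in addition, camera did not call it (adjusted p = 0.135).

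**Figure D2:**
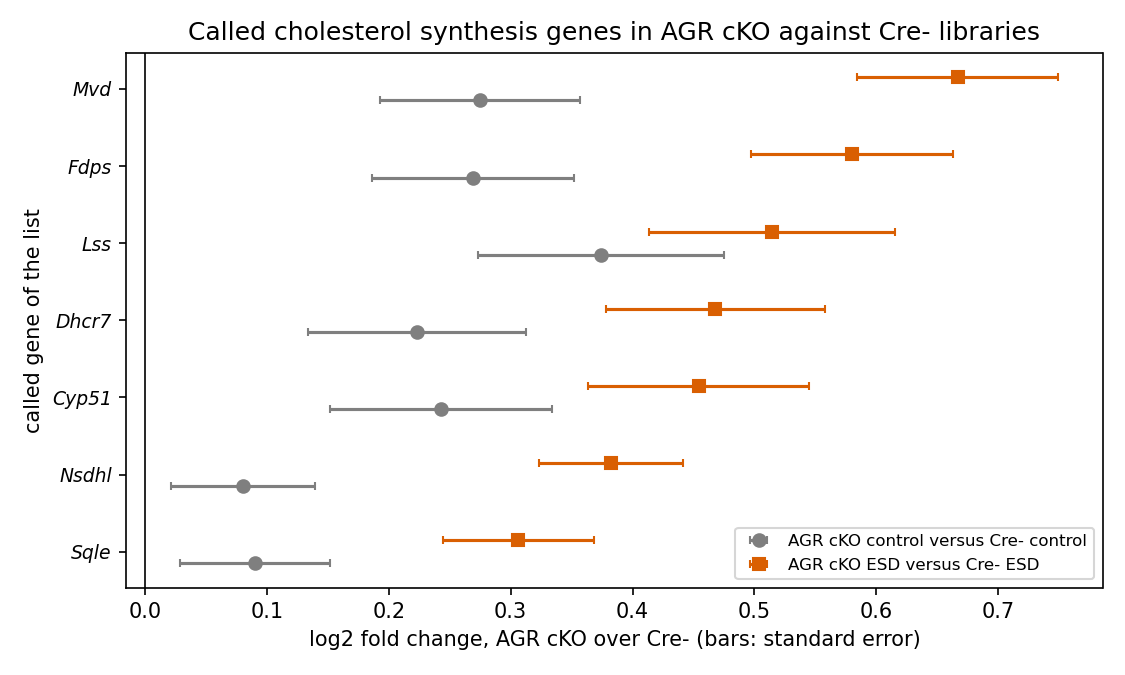
Log2 fold change and standard error of the 7 called cholesterol synthesis genes in AGR cKO against Cre- libraries, for control animals (grey circles) and under ESD (orange squares), n = 3 libraries per group. All 7 lie above 0 in both, from Sqle at 0.31 ± 0.06 to Mvd at 0.67 ± 0.08 under ESD, where their calls were made.

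Glucocorticoid-responsive genes were lower in 22 of 23 (median -0.84, camera adjusted p = 4.69e-11), 3 of them called (Hif3a, Zbtb16 and Mfsd2a at -1.48 ± 0.30) and 15 adjusted over the list alone; with an estimated correlation the adjusted p = 0.371. Fkbp5 was at -3.03 ± 0.75, Tsc22d3 at -1.34 ± 0.31 and Sgk1 at -0.88 ± 0.29, short of the threshold (adjusted p = 0.0903, 0.0724 and 0.182). Without Cre- ESD 3, in which Fkbp5, Tsc22d3 and other members stood far above the other Cre- ESD libraries, Fkbp5 was at -1.05 and Tsc22d3 at -0.75, and without Cre- ESD 2 Fkbp5 passed (adjusted p = 0.0455). Among engulfment genes Mertk and Gas6 fell, while Megf10 (206 ± 28.6 against 197 ± 40.5 CPM) and Axl (437 ± 19.0 against 435 ± 33.6 CPM) differed by less than their spread; the list as a whole was not called (11 of 20 lower, adjusted p = 0.704). Among synapse-regulating factors Sparc, a secreted matrix protein, fell by 0.80 ± 0.14 on the log2 scale and Nlgn2, a synaptic adhesion protein, rose by 0.45 ± 0.08 (adjusted p = 0.0307 and 0.031). That list was called as higher (11 of 17, adjusted p = 0.0344), not with an estimated correlation (adjusted p = 0.371) and not without Cre- ESD 3 (adjusted p = 0.0648).

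Most genes of the A1-type, A2-type and pan-reactive lists were lower in AGR cKO under ESD. S100a10 of the A2-type list rose, while Cd109, a surface glycoprotein of the A2-type list, fell by 1.28 ± 0.21 and Cxcl10, a chemokine of the pan-reactive list, by 0.75 ± 0.14 on the log2 scale (adjusted p = 0.0284 and 0.0326). The A2-type (10 of 12 lower, adjusted p = 0.0255) and A1-type lists (10 of 10 lower, adjusted p = 0.00271) were called by camera and the pan-reactive list was not (10 of 13 lower, adjusted p = 0.069). The A1-type and A2-type lists both had an adjusted p = 0.371 with an estimated correlation. Atf3, a stress-induced transcription factor, fell by 0.66 ± 0.13 on the log2 scale (adjusted p = 0.0431); its list of immediate early and heat shock genes (14 of 17 lower, adjusted p = 0.0344) and interferon-stimulated genes (15 of 18 lower, adjusted p = 0.0344) were called. With an estimated correlation these 2 had an adjusted p = 0.705, and without Cre- ESD 3 the camera adjusted p was 0.526 and 0.108. Interferon-stimulated genes changed direction without AGR cKO ESD 1 (adjusted p = 0.59). The A1-type call was lost without AGR cKO ESD 1 (0.0645) and the A2-type call without Cre- ESD 1 (0.0868) or AGR cKO ESD 3 (0.0987). Astrocyte markers (12 of 20 lower, adjusted p = 0.632), cell cycle (17 of 21 higher, 0.142), lysosome (12 of 22 lower, 0.315), and nuclear oxidative phosphorylation genes (14 of 22 lower, 0.404) were not called.

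Markers of other cell types were lower in AGR cKO ESD than in Cre- ESD libraries as well. This held for microglia and macrophages (19 of 20, median -1.07, adjusted p = 1.99e-08), endothelium (14 of 14, -1.02, 0.000204), mural cells and fibroblasts (13 of 13, -0.46, 0.00138), erythroid genes (5 of 5, -1.56, 5.33e-06), ependyma (7 of 10, -0.62, 0.011) and neurons (17 of 19, -0.41, 0.00854). With an estimated correlation their adjusted p lay between 0.371 and 0.471, and the mural call was lost without Cre- ESD 3 (adjusted p = 0.0648), the neuron call without Cre- ESD 1 (0.111) and the ependymal call without AGR cKO ESD 3 (0.14). Of the 13 lists called in this comparison, 5 were called in every fit without 1 library: glucocorticoid-responsive, cholesterol synthesis, microglial, endothelial and erythroid genes. Grin1 rose by 0.88 ± 0.16 (adjusted p = 0.0326) while most neuron markers were lower. Oligodendrocyte (10 of 13 lower) and precursor markers (7 of 12 lower) were not called (adjusted p = 0.315 each).

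**Figure D3:**
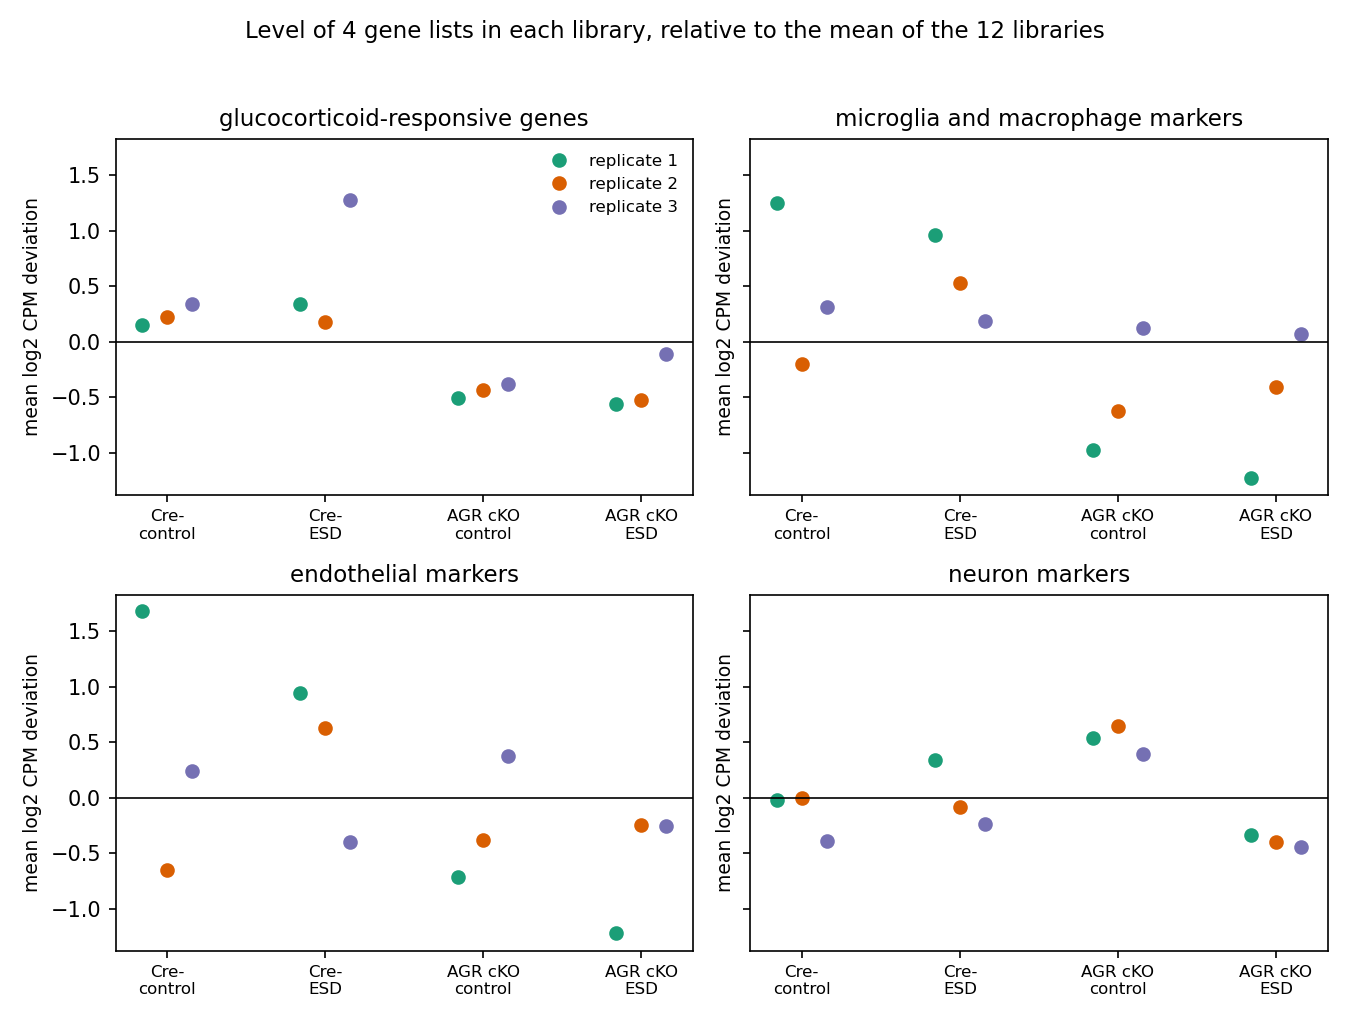
Mean log2 CPM of the genes of 4 lists in each of the 12 libraries, as the deviation from the mean of all libraries, with replicate numbers in colour. The glucocorticoid-responsive level is below 0 in the 6 AGR cKO libraries and 1.28 in the third Cre- ESD library, and the microglial level runs from 1.25 in the first Cre- control to -1.23 in the first AGR cKO ESD library.

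Genotype differences under ESD had the same direction in control animals for 191 of the 200 genes (105 of 112 higher and 86 of 88 lower), in libraries that are not shared between the comparisons. Of the 200, 133 also had an unadjusted p under 0.05 in control animals, and all 3 genes called there were among them. Over all genes tested, 10.2% had such a p in control animals, and the log2 fold changes of both comparisons had a Pearson r of 0.361. Both comparisons share 1 spread estimate per gene from all 12 libraries, which also entered the choice of the 200. The p-values in control animals are therefore no independent support for the 200.

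The interaction asks whether the stress difference depends on the receptor. Among the genes with the smallest p were Fzd10, a Wnt receptor, at 1.16 ± 0.21, Sez6l2 at -1.38 ± 0.25 and Slc17a7 at -2.37 ± 0.46, together with Gm40469, which had no count in Cre- control (adjusted p = 0.904 each). Zbtb16 had an interaction of -2.24 ± 0.48 (adjusted p = 0.981). Mertk was at -0.22 ± 0.24 (adjusted p = 0.999) and at -0.000466 without Cre- ESD 3, and Nr3c1 at -0.15 ± 0.17 (adjusted p = 0.999). The 95% interval of the Mertk interaction ran from -0.74 to 0.31.

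In edgeR 0 genes were called for the interaction, with 860 at an unadjusted p under 0.05, while DESeq2 called 9 and limma-trend on TPM 0. Camera called 6 lists, none kept with an estimated correlation (adjusted p = 0.0604 to 0.668). Neuron markers had an interaction below 0 in 18 of 19 (median -0.91, adjusted p = 2.29e-11, and adjusted p = 0.0604 with an estimated correlation), 6 of them passing when adjusted over the list alone. Without Cre- ESD 1 the list passed with an estimated correlation (0.0354). The other calls were for mural cell, erythroid, interferon-stimulated and mitochondrial genes, all with interactions below 0 in most members. Cholesterol synthesis genes had an interaction above 0 in 18 of 20 (median 0.19, adjusted p = 1.01e-06, and adjusted p = 0.173 with an estimated correlation), with Nsdhl at 0.30 ± 0.08 and Mvd at 0.39 ± 0.12. The 6 calls stayed without Cre- ESD 3, where endothelial markers (adjusted p = 0.0109) and A2-type genes (adjusted p = 0.0184) were called in addition, and not with an estimated correlation (0.647 and 0.561). Neuron, erythroid and cholesterol genes kept their call in every fit without 1 library. Mural markers lost it without Cre- control 2 (adjusted p = 0.0682), interferon-stimulated genes without Cre- control 2 (0.146) or AGR cKO ESD 1 (0.425), and mitochondrial transcripts without Cre- control 1 (0.247) or AGR cKO ESD 2 (0.0921).

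ESD effects across genotypes were compared over the 19163 genes, where the log2 fold changes had a Pearson r of 0.079 and a Spearman rho of 0.208, a description across genes, which are not independent replicates. The 137 genes with an unadjusted p under 0.05 in both compare with 104 expected if the p-values were independent, and 106 of them had the same direction. Both comparisons share 1 spread estimate per gene, so their p-values are not independent and the excess does not by itself show shared stress differences. The r was 0.211 among genes above 1 CPM in at least 3 libraries. It was 0.00505, 0.0361 and 0.0424 without Cre- control 1, 2 and 3, 0.0199 without AGR cKO control 3, 0.0312 and 0.0103 without Cre- ESD 1 and 2, and 0.0433 and 0.0223 without AGR cKO ESD 1 and 2.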

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

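Among the tests of this part, those for carried-over cells, handling, positions of called genes and linked DNA were chosen only after the result was seen. So were those for every other cell type in control and under ESD and for the marker covariate. The interaction tests of the lists were set before the data were examined. The share of genes lower without the receptor, the correlation between copies and the microglial losses concern patterns found in the data. These were set before the tests were run, not before the data were seen.

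The stress difference of 6 lists depended on genotype by camera with the preset correlation, which is why they are given here. The adjusted p was 2.293e-11 for neuron markers (18 of 19 interactions below 0, median -0.91, and adjusted p = 0.0604 with an estimated correlation) and 0.0002213 for mural cell and fibroblast markers (13 of 13 below 0, median -0.59, and adjusted p = 0.591). Erythroid genes had 0.0001255 (5 of 5 below 0, median -0.998, and adjusted p = 0.588) and interferon-stimulated genes 0.0006082 (15 of 18 below 0, median -0.39, and adjusted p = 0.668). Cholesterol synthesis genes had 1.009e-06 (18 of 20 above 0, median 0.19, and adjusted p = 0.173), and mitochondrial transcripts 0.002757 (13 of 13 below 0, median -0.22, and adjusted p = 0.668). The second value in each case is the one with an estimated correlation. Of the 30 splits of the libraries tried, 25 called at least as many lists as the real one, which called 6 against a highest other of 12, so chance was not excluded for these list calls.

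Glucocorticoid-responsive genes stood far above the other Cre- ESD libraries in Cre- ESD 3: Fkbp5 was at 103 CPM against 11.1 and 9.93, Plin4 at 37.4 against 4.17 and 3.12, and Tsc22d3 at 367 against 140 and 152. Microglia, neurons, oligodendrocytes, their precursors, endothelial or erythroid cells carried over into that library are argued against, since the highest median ratio of their markers to the higher of the other Cre- ESD libraries was 0.7426. Mural cells, fibroblasts or ependyma carried over stay open: the highest median ratio was 1.275, with 10 of 13 mural and 7 of 10 ependymal markers above both other Cre- ESD libraries and 0 of them 2-fold. Transcription driven by the receptor in the animals of that library stays open. Of 186 genes at least 2-fold above both other Cre- ESD libraries, 61.83% were lower in AGR cKO control than in Cre- control. The exact interval was 54.4% to 68.8%, around the bound of 60% set before this test was run. It treats the genes as independent, though they were chosen for being high in 1 library, and measures no spread between animals. The share was 51.6% among all genes at that level and 60.3% among the 179 outside the list. A response to dissociation and handling cannot be told apart from these, since 1 library, Cre- control 3, was higher in immediate early and heat shock genes (0.43 against 0.27), with a glucocorticoid-responsive level of 0.34 against 1.28, and this test rests on single libraries.

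Genes called for genotype, averaged over ESD, lay close together on single chromosomes. In 1 window on chromosome 4 there were 17 calls where 4.29 were expected, a count that 0.0002 of random draws reached. Of these 17 calls, 14 are near-identical copies, which the draws treat as separate genes, so this test cannot decide on chance there. With the copies counted once, the highest count in a window was 11, on chromosome 8. Chance positions are argued against on chromosome 10, where 0.0055 of draws had a window with as small a p as that of 9 calls against 1.67 expected. Reads shared between near-identical copies on chromosome 4 had the values they need. Over 14 called copies (41887610 to 42804092) the median correlation of deviations from group means was 0.5374, against a highest of 0.267 in random gene sets of like level. The sets were matched on level alone, so genes that vary together for another reason could reach such a value too. The correlation is within groups and cannot decide why 34 of 34 tested genes of the block were lower in AGR cKO. With these copies counted as 1 gene, chance positions were not excluded for windows on chromosomes 19 (7 calls, 0.0675 of draws), 18 (6 calls, 0.223) and 8 (11 calls, 0.301, or 0.105 by the count). DNA linked to the Cre transgene cannot be told apart from receptor loss, since it is confounded with genotype. The smallest interaction adjusted p among these genes was 0.9991. Per the labels both genotypes carry the floxed allele, so DNA linked to that allele is not confounded with genotype in this way.

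Mertk was lower in AGR cKO libraries together with microglial and endothelial markers. Fewer carried-over microglia alone are argued against, since 0 of 20 microglial markers lost as many CPM under ESD as Mertk, which lost 314 CPM where Csf1r, the highest, lost 89.9. A lower share of every other cell type is argued against in control, because 89.47% of neuron markers were higher there in AGR cKO; under ESD it stays open for the marker lists, of which 8 of 8 had most genes lower and 6 were called. A lower microglial and endothelial share as the whole cause of lower Mertk under ESD is argued against. With that level as a covariate Mertk was at -1.12 ± 0.18 (-0.97 ± 0.17 without), and its r with the level within groups was -0.459. Mural, erythroid, ependymal and neuron markers are not in the covariate, so the covariate fit cannot decide on a lower share of those cells. Loss of the glucocorticoid receptor in astrocytes had the value it needs, an adjusted p of 0.02805 in the covariate fit. It stays a hypothesis, as a Cre effect apart from it was not analysed here and cells outside the covariate were not adjusted for.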

How the results depend on the processing

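Robust moderation, the microglial and endothelial covariate and the list tests with 1 library left out were tests chosen only after the result was seen. Of 185 named values, 38 were called, and these kept direction in every setting run on whole genes, unlike single Nr3c1 transcripts, given below. The settings reuse libraries in which the calls were made, so kept direction is no separate support. All 38 kept their call with DESeq2, median-of-ratios and upper-quartile factors, genes above 1 CPM and robust moderation, 30 without a filter, 20 with the covariate, 29 and 30 with limma-trend on TPM, 2 with only the groups compared, and 2 (without Cre- ESD 1) to 36 (without Cre- control 1) with 1 library left out. With 1 library left out, a group of 2 is assumed to vary like the others. The cause was not tested for any value below, except that fits of fewer libraries have fewer residual degrees of freedom. Floors of 3 counts cover counting error only.

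Genes called with DESeq2 were 24 and 17 for stress in Cre- and AGR cKO, 265 and 783 for genotype in control and under ESD, and 9 for the interaction. At an unadjusted p under 0.05 and 2-fold they were 161, 247, 570, 576 and 256. The covariate gave 1 for stress in AGR cKO and 112 for genotype under ESD. Only the groups compared gave 31 for genotype in control and 0 under ESD, where no filter gave 100 and 2-fold in addition 54. Leaving out 1 library gave 0 to 1 for stress in Cre-, 0 to 0 in AGR cKO, 0 to 63 for genotype in control, 2 to 280 under ESD and 0 to 0 for the interaction.

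Values near 0 changed sign. Megf10 for stress in Cre- was 0.007612 (DESeq2), 0.006941 (median-of-ratios), 0.009791 (upper quartile), 0.01413 (no filter), 0.003559 (above 1 CPM), 0.00809 (groups compared) and 0.01124 (covariate). In AGR cKO it was -0.0005929 (above 1 CPM), -0.03965 and -0.04035 (TPM plus 1 and 0.1) and -0.02478 (covariate), and for the interaction -0.007161 (no filter), -0.004151 (above 1 CPM), -0.0002179 and -0.0004383 (TPM) and -0.03602 (covariate). Tsc22d3 for stress in AGR cKO was 0.0004209 (upper quartile), and Aldh1l1 for genotype -0.07877 in control and -0.04191 under ESD (covariate). With only the groups compared, Nr3c1 under ESD was -1.279 (adjusted p = 0.146) and Mertk -0.9729 (0.158), both past the threshold no longer.

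Single Nr3c1 transcripts, control then ESD, were not called: -0.9993 and -0.9372, -1.209 and -1.32, -1.709 and -1.559, 0.2638 and -0.8886, -2.221 and -1.186, -1.669 and -0.08762, 1.395 and 2.207, -0.4953 and -2.919, -0.4323 and -0.3905, -0.7893 and -0.3468, -1.092 and -1.697, 0.04015 and 0.1447, -1.322 and -0.7564, -2.285 and -0.7421. The Nr3c1 transcripts at -0.9993, -1.209 and -1.709 in control held 11.1%, 23.2% and 41.3% of its counts. Those with a value above 0 held 4.67% (0.2638 ± 2.09 in control), 2.17% (1.395 ± 0.82 and 2.207 ± 0.85) and 0.67% (0.04015 ± 1.28 and 0.1447 ± 1.28). The Mertk transcripts with 83.2% and 16.8% of its counts were at -1.064 and -0.563 under ESD and at -0.3753 and 0.4577 for the interaction. Over all transcripts 6 and 2 were called for stress in Cre- and AGR cKO, 1 and 5 for genotype and 4 for the interaction. The r across genotypes was 0.2109 above 1 CPM.

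With 1 library left out the log2 fold changes were: Nr3c1 control -1.175 to -1.069; Mertk control -0.8388 to -0.706 and ESD -1.086 to -0.756. Megf10 ran from -0.1213 to 0.1273 and -0.1137 to 0.1692 for stress in Cre- and AGR cKO, -0.1917 to 0.0506 and -0.18 to 0.09389 for genotype in control and under ESD, and -0.1196 to 0.1713 for the interaction. Tsc22d3 ran from -0.1407 to 0.7005 and -0.1842 to 0.1381 for stress, and -0.7054 to 0.1339 for the interaction. Sgk1 ran from -0.1737 to 0.3612, -0.3109 to 0.1356 and -0.5066 to 0.08646 in these. Axl ran from -0.08578 to 0.02185 for stress in AGR cKO and -0.05875 to 0.05041 for genotype under ESD, and Aldh1l1 from -0.0991 to 0.08878 and -0.07341 to 0.1995 for genotype and -0.07857 to 0.1777 for the interaction. The r across genotypes ran from 0.005048 to 0.08872.

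Lists that turned in a fit without 1 library had these camera adjusted p-values over the 12 fits. For stress in Cre- they were 2.399e-06 to 0.6303 for glucocorticoid-responsive genes, 0.0009476 to 0.9972 for endothelial markers and 0.001446 to 0.952 for cell cycle genes. For stress in AGR cKO they were 0.01128 to 0.994 for microglial markers, 5.051e-10 to 0.87 for interferon-stimulated genes and 0.0004922 to 0.4425 for cell cycle genes. Cell cycle genes ran from 0.00342 to 0.9004 for genotype in control, interferon-stimulated genes from 5.7e-06 to 0.5901 under ESD, and nuclear oxidative phosphorylation genes from 0.03785 to 0.9229 for the interaction. Of 4, 11, 8, 13 and 6 lists called, 1, 4, 5, 5 and 3 were called in every one of these fits.

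Samples share only a replicate number: 18 same-number pairs had r of -0.10 to 0.23 and 8 of 12 libraries correlated best with their own number, a hint from the data and not the design. With replicate number as a block edgeR called 2 genes for genotype in control, 244 under ESD and 0 in the other comparisons of 2 groups and the interaction, and every camera list call was kept at the preset correlation. With an estimated correlation and the block, cholesterol synthesis for genotype under ESD had an adjusted p = 0.135 and was not called, while neuron markers were called for stress in AGR cKO (0.0472) and for the interaction (0.0476).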

Other observations

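The averaged contrasts and their tests in this part were chosen only after the planned results were seen, while the counts over other splits of the libraries for the 5 comparisons above were set beforehand.

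Averaged over control and ESD, the genotypes could be compared with 6 libraries on each side. Vcan, encoding versican, rose from 110 ± 22.99 to 253 ± 17.0 CPM in AGR cKO (1.21 ± 0.13, adjusted p = 0.00382), and Tnc, encoding the matrix glycoprotein tenascin C, from 358 ± 107 to 711 ± 99.6 CPM (0.99 ± 0.19, adjusted p = 0.0226). St6gal2, a sialyltransferase, rose by 1.38 ± 0.29, Cnih3, an auxiliary protein of AMPA receptors, by 1.21 ± 0.22, Alk, a receptor tyrosine kinase, by 1.05 ± 0.17, and Fras1, a basement membrane protein, by 0.92 ± 0.14 (adjusted p = 0.00802 to 0.0298). Etnppl, an ethanolamine-phosphate phospho-lyase of astrocytes, fell from 26.1 ± 27.4 to 1.81 ± 1.41 CPM (-3.79 ± 0.75, adjusted p = 0.0235, and -3.01 ± 0.63, adjusted p = 0.0357, without Cre- ESD 3). Sult1a1, a sulfotransferase, fell by 1.84 ± 0.33 and Cebpa, a transcription factor, by 1.54 ± 0.33 on the log2 scale (adjusted p = 0.0154 and 0.03), and by 1.45 ± 0.23 and 1.08 ± 0.19 without Cre- ESD 3 (0.0138 and 0.0172). Plin4, a lipid droplet protein, fell from 9.14 ± 13.9 to 0.985 ± 0.303 CPM (-2.85 ± 0.61, adjusted p = 0.0296), with 37.4 CPM in Cre- ESD 3 and 1.96 to 5.72 CPM in the other Cre- libraries; without Cre- ESD 3 it was at -1.83 ± 0.31 (adjusted p = 0.0157). Hif3a fell from 178 ± 96.3 to 33.3 ± 8.48 CPM (-2.37 ± 0.25, adjusted p = 0.0032). In edgeR 668 genes were called, 297 higher and 371 lower, of which 183 were also called under ESD alone. Without Cre- ESD 3 the count of genes called for the genotype effect averaged over ESD was 467.

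Cholesterol synthesis genes were higher in 20 of 20 in this contrast, 11 of them called (median 0.26, camera adjusted p = 2.86e-16, and adjusted p = 0.0267 with an estimated correlation). Glucocorticoid-responsive genes were lower in 22 of 23, 9 of them called (median -0.77, adjusted p = 1.84e-13, and adjusted p = 0.366 with an estimated correlation). Marker lists of other cell types were lower as well: microglia and macrophages in 19 of 20 (median -1.10, adjusted p = 2.93e-11), endothelium in 14 of 14 (-1.04, 7.58e-05), erythroid genes in 5 of 5 (-1.04, 0.000168) and ependyma in 8 of 10 (-0.79, 7.58e-05), 4 of them called. With an estimated correlation the adjusted p was 0.373 for these lists and 0.528 for endothelium. Averaged over genotypes, edgeR called 0 genes for stress, with 1987 at an unadjusted p under 0.05 and a smallest adjusted p of 0.438; DESeq2 and limma were not run on this contrast.

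Other splits of the same libraries were tested for each count. For the averaged genotype contrast 1 of 30 splits, the real one, reached 668 calls and the highest other gave 1. That argues against chance for this count, though 1 of 30 is the smallest share these splits can give. The contrast itself was chosen after the planned results were seen. For the interaction the real split called 0 genes, a count that 30 of 30 splits reach by necessity, and the highest other called 12, with a median of 0; chance is not excluded. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real split and the highest other called 0 and 1 genes for stress in Cre- (10 of 10 as large), 0 and 1 for stress in AGR cKO (10 of 10), 3 and 1 for genotype in control (1 of 10) and 200 and 0 for genotype under ESD (1 of 10). For lists the real split and the highest other called 4 and 12 (9 of 10 as large, median of the others 9), 11 and 12 (4 of 10, median 9), 8 and 15 (7 of 10, median 10) and 13 and 11 (1 of 10, median 9). Camera with a preset correlation thus called a median of 9 to 10 lists in splits that mix the groups. The lists of the interaction had 25 of 30 splits as large.

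In 16 of 110 list tests the median, the mean and the direction of the camera test differed in sign, and 0 of these were called.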
